A study of Mus musculus with 6 samples.

How the data were processed

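RNA was sequenced from sorted tumor cells of subcutaneous MC38 tumors. The 6 libraries, 3 control and 3 labelled Zfx-KO, were assigned by the genotype field of the labels. Per the labels' protocols, tumors were minced and digested with collagenase, dispase and DNase, total RNA was taken from the sorted cells, and libraries were made from a small amount of cDNA with a transposase-based kit and sequenced from a single end. The labels do not name the marker used for the sort, the strain of the mice, or any batch, date or pairing, and replicates were numbered in the order of their records. Extraction is described with different kits in the design text and in the protocol of the samples. The submitters' processing notes name the genome builds GRCh38 and mm10 without a role, and the aligner and counter are not given in the sources used here.

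The deposited table held log2 values for 52636 genes, with 0 columns of other samples. Values of genes with no reads stood at a common floor of -5.48715, and the linear values of each library summed to about 1.0012e+06, so the values were read as log2 CPM (reads of a gene scaled to the library total) with a prior of 1 read on average scaled to library size. Under this reading all low values, those below 2000 reads, gave whole reads within 0.05 reads, and the totals recovered this way were the depths: 42392848, 42962577 and 42723982 reads for control replicates 1 to 3, and 37763096, 38228435 and 65050908 for the replicates labelled Zfx-KO. At these depths 3 reads correspond to 0.0461 to 0.0794 CPM. Fold changes were on this log2 scale with the prior, which understates changes of scarce genes. Intervals and bounds from reads cover counting error only, since reads copied by PCR are not independent molecules.

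Of the gene identifiers, 99.7% were found in GENCODE M21 (GRCm38) and 85.6% had identical start and end there; chromosomes were taken from that annotation and start and end from the deposited table. Symbols were those of the table, in which 27 had been turned into dates. Some genes present in nearly every cell stood close to the floor, such as Gapdh at -2.21 and Rps6 at -1.65 log2 CPM in the controls, so reads shared with pseudogenes or paralogs appear to have been left out, and values of genes with close copies are uncertain. Strand was not stated, so genes that overlap an antisense partner may hold its reads.

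Genes were kept when above the floor in at least 3 libraries with a mean of at least 1 log2 unit above it, which left 20094. The libraries labelled Zfx-KO were compared with the controls with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes test with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with a second count for changes of at least 2-fold. The 24 gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. Zfx was also tested with an exact permutation test. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0.

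Before the data were examined, the lists, the tests, the alternatives and the rule for named genes were fixed. The rule took Zfx, Zfy1, Zfy2, Zfp711, Thy1, Ptpmt1 and Idh2; the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, groups without overlap, a mean in the higher group at least 3 log2 units above the floor, and a symbol that is not a predicted gene, pseudogene, microRNA or snoRNA name; and up to 4 members with the smallest p from each list, or 2 where none passed. Some genes that the rule took are not reported here. Genes chosen after their values were seen are named as such; Xist and the homeobox, protocadherin, mitochondrial and imprinted genes given by name belong to them, except Igf2 and Rian, which the rule took. Within groups, replicate libraries differed by more than sampling noise (chi-square per gene of 13.2 to 25.4), and each was counted as 1 replicate. Technical differences between libraries could also give this spread, so it does not show that they came from separate animals. The alternatives were no filter or a filter 3 log2 units above the floor, equal medians, quantile normalization, no variance trend, a robust variance prior, sample weights, the pseudocount times 0.25 and 4, leaving out each library, and for lists the estimated correlation, fry and ranks. limma voom on the recovered reads and thinning of the reads to the shallowest library were added after seeing the data.

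The test was checked on simulated data for the comparison of the libraries labelled Zfx-KO with the controls, in 20464 genes. It recovered 26% of the genes changed 1.25-fold, 56.2% of those changed 1.5-fold, 67.3% of those changed 2-fold and 82% of those changed 4-fold, and called 5 of 20233 unchanged genes. The simulated genes were independent and shared a dispersion (variation beyond counting noise) of 0.00367, taken from the more abundant genes. Only 48 to 50 genes of each size and the G2/M genes were changed. These rates do not carry over to the real data. There 8927 genes were called, some scarce genes varied far more, and correlations within a list reached 0.972.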

Results

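The transcriptome of MC38 tumor cells recovered from mice was compared between a control line and a line in which Zfx had been targeted. MC38 is a mouse colon adenocarcinoma cell line, and Zfx is an X-linked zinc finger transcription factor. Cells of the M1E5 line were injected under the skin of female mice, the tumors were digested, and the tumor cells were collected by flow cytometric sorting before RNA sequencing. The control line carried the label Thy1.1. The targeted line, in which Zfx was edited with CRISPR ribonucleoprotein complexes, carried the label Thy1.2, the other allelic form of the surface protein Thy1. Each group had 3 libraries, with 42392848, 42962577 and 42723982 reads in the controls and 37763096, 38228435 and 65050908 in the libraries labelled Zfx-KO. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. The genotype and the Thy1 label changed together in all 6 libraries.

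Zfx itself, on chromosome X from 94074631 to 94123407 in GRCm38, was higher in the libraries labelled Zfx-KO, against the direction that the label names. Its level was 5.67 ± 0.21 log2 CPM (SD, n = 3) in the controls and 6.31 ± 0.09 (SD, n = 3) in the libraries labelled Zfx-KO, a difference of 0.64 (SE 0.10, limma adjusted p = 0.000473), which was 0.42 with equal medians (0.00249). The control libraries stood at 5.68, 5.88 and 5.46, and those labelled Zfx-KO at 6.30, 6.41 and 6.22. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The value covers reads over the whole gene, and the cut site is not given in the labels, so an edited transcript that is still made would be counted too. For this reason the direction of every difference below refers to the label and not to a measured loss of Zfx. The related genes Zfy1 and Zfp711 had 0 reads in all 6 libraries, and Zfy2 had 1 read in the libraries labelled Zfx-KO. At these depths 0 reads allow a level of up to 0.0461 to 0.0794 CPM per library. Reads shared with paralogs or pseudogenes appear to have been left out, so these counts and the bound may cover only unique reads. The same may hold for the level of Zfx.

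Ptpmt1 and Idh2, mitochondrial enzyme genes described as depending on Zfx in leukemia cells, were both lower in the libraries labelled Zfx-KO. Ptpmt1 fell from 5.31 ± 0.03 to 4.04 ± 0.12 log2 CPM (SD, n = 3 each, limma adjusted p = 9.71e-07), and Idh2 fell from 7.79 ± 0.09 to 7.31 ± 0.06 (limma adjusted p = 0.000166). Thy1, whose alleles the read totals do not separate, rose from 7.51 ± 0.04 to 8.68 ± 0.15 (limma adjusted p = 1.49e-06).

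**Figure D1:**
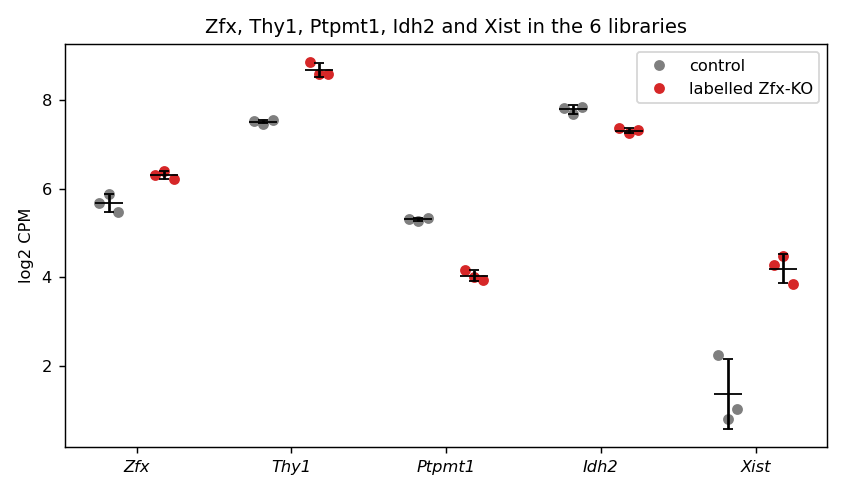
Level in log2 CPM of Zfx, Thy1, Ptpmt1, Idh2 and Xist in each library (points), with the mean and SD of the 3 control libraries and the 3 libraries labelled Zfx-KO (black). Zfx and Thy1 were higher, and Ptpmt1 and Idh2 lower, in every library labelled Zfx-KO than in any control.

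The groups differed in a large part of the transcriptome, with the larger changes mostly rises of scarce genes. Of 20094 genes tested, 8927 passed an adjusted p of 0.05 in limma, 5003 higher and 3924 lower in the libraries labelled Zfx-KO. Changes of at least 2-fold were found in 3066 genes, 2332 higher and 734 lower. Among the 7284 genes with a mean under 0 log2 CPM over all 6 libraries, 1602 were higher by at least 2-fold and 241 lower. Among the 4548 genes with a mean between 5 and 7 log2 CPM, 69 were higher and 114 lower. The values of the groups did not overlap for 54.1% of the genes tested, where chance gives 10%. Correlations across genes were 0.984 to 0.989 within groups and 0.944 to 0.955 between them, and the first principal component, which held 73.2% of the variance, separated the groups. The balance of rises and falls rests on the scaling between libraries. Calls were higher in 56.0% of cases as deposited, in 33.7% with equal medians, which lowers every fold change by 0.21 on the log2 scale, and in 47.5% with quantile normalization. For changes of at least 2-fold these shares were 76.1%, 62.9% and 50.3%.

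The 12 largest rises were of genes with few or no control reads, on which their order rests. Fbln2, which encodes the matrix protein fibulin-2, rose by 9.54 on the log2 scale (SE 0.86, limma adjusted p = 1.28e-05), from -2.17 ± 2.33 to 7.38 ± 0.24 log2 CPM (SD, n = 3). Svep1, a matrix and adhesion protein gene, rose by 9.14 (SE 0.23, limma adjusted p = 8.58e-09), and Gpx3, a secreted glutathione peroxidase, by 9.15 (SE 0.33, limma adjusted p = 4.81e-08). Serping1, the C1 inhibitor of complement, rose by 9.12, Fndc1 by 9.28, the guidance ligand Slit3 by 8.95 and Itih5 by 8.76, each with at most 22 reads in all controls together. Adamts2, a procollagen protease gene, rose from -3.23 ± 1.06 to 5.77 ± 0.20 log2 CPM. Without control replicate 2 the rises were 8.40 for Fbln2, which had 1 read there, 8.48 for Fndc1 and 8.38 for Adamts2. Without control replicate 3 that of Fbln2 was 10.73, and without control replicate 1 that of Itih5 was 9.38. Genes with 1 to 3 control reads are given as ratios of pooled reads with a 95% exact interval. The Wnt antagonist Sfrp2 had 2 control reads and a ratio of 1284 (interval 355 to 10608), the imprinted long noncoding RNA Rian had 1 and a ratio of 1586 (284 to 62660), and the matrix gene Efemp1 had 2 and a ratio of 932 (258 to 7702). Abcc9, a potassium channel subunit gene of pericytes, had 0 control reads and 1297 reads in the libraries labelled Zfx-KO, which makes it at least 393-fold higher against 3 reads over the group.

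The 12 largest falls included Slain1, Ppp1r9a and Sim2. Slain1, a microtubule plus-end protein gene, fell by 5.94 on the log2 scale (SE 0.59, limma adjusted p = 2.31e-05), and Ppp1r9a, the actin-binding protein neurabin, fell by 5.79 (SE 0.28, limma adjusted p = 2.16e-07), from 4.61 ± 0.22 to -1.19 ± 0.62 log2 CPM (SD, n = 3). The transcription factor gene Sim2 dropped by 5.74, the C-type lectin gene Clec1a dropped by 5.72 and the RNase gene Zc3h12b dropped by 5.35. The imprinted growth factor gene Igf2 fell by 5.20 (SE 0.20, limma adjusted p = 6.14e-08), from 5.27 ± 0.35 to 0.08 ± 0.31. Mvb12b, of the endosomal sorting machinery, fell by 4.90 from the highest control level of these genes, 6.24 ± 0.14 log2 CPM. The remaining 5 were Slc35f1, which stood at 2.52 in the controls and -2.48 in the libraries labelled Zfx-KO, the ephrin receptor gene Epha7 with a log2 fold change of -4.86, Caskin1 with -4.83, CT571266.1 with -4.83 and Bend4 with -4.81. Without replicate 1 of the libraries labelled Zfx-KO the log2 fold changes were -5.13 for Slain1, -4.56 for Zc3h12b and -5.66 for Slc35f1, and without replicate 2 that of Slc35f1 was -4.06.

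**Figure D2:**
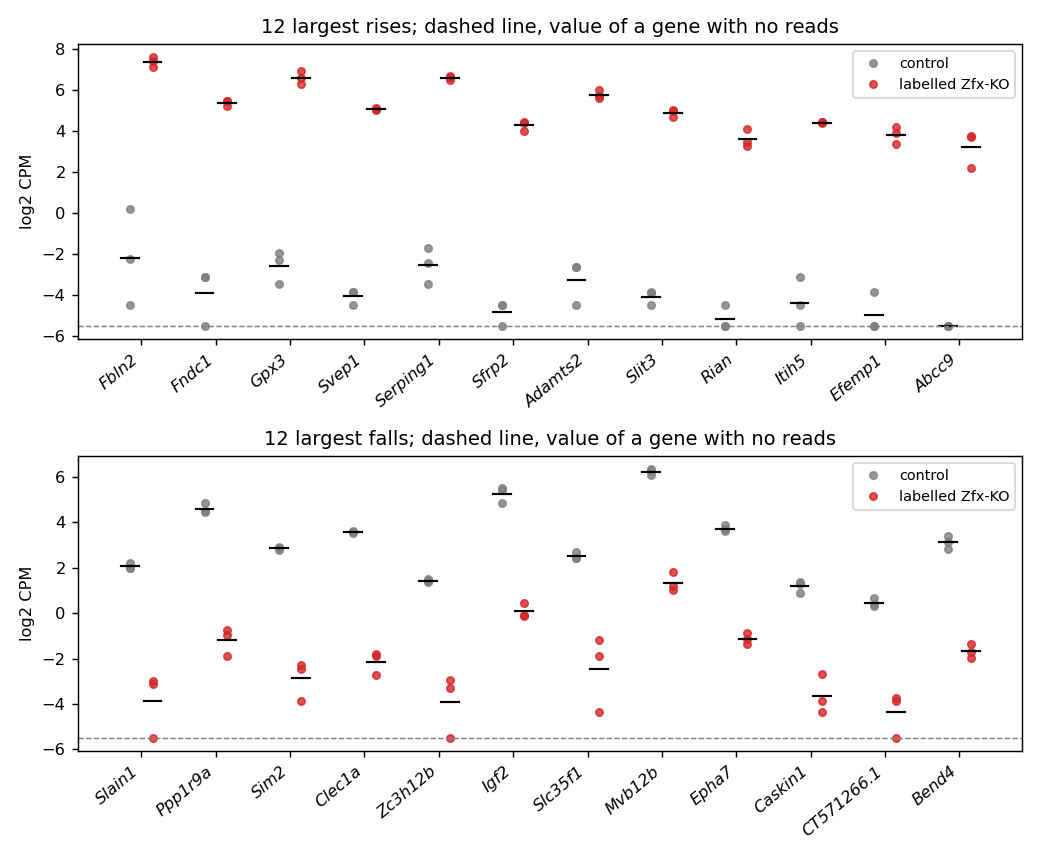
Level in log2 CPM of the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom) in each control library and each library labelled Zfx-KO, with group means as black bars; the dashed line marks a gene with no reads. The 2 groups are apart for all 24 genes, and most of the risen genes lie near the dashed line in the controls.

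Most markers of endothelial cells and pericytes rose, though not in one pattern over the libraries. Of 20 tested, 19 rose and 1, Ramp2, fell, with the same counts adjusted over the list alone, and the median log2 fold change was 3.49, also with Abcc9 at its bound, and 2.78 without control replicate 2 (limma camera adjusted p = 7.64e-08; adjusted p = 0.517 with an estimated correlation). The endothelial adhesion molecule Pecam1 rose from 4.27 ± 0.26 to 6.71 ± 0.22 log2 CPM (SD, n = 3), Plvap rose by 2.17 and Mcam by 4.84. Among genes chosen after their values were seen, the pericyte gene Rgs5 rose by 8.12 (8.91 and 7.47 without control replicates 1 and 2) and the VEGF receptor gene Kdr by 4.41, from -3.44 to 0.97 log2 CPM, while Ramp2 fell by 0.66. Among the libraries labelled Zfx-KO, Rgs5, Abcc9, Mcam and Plvap were lowest in replicate 3 (5.21, 2.19, 3.43 and 3.46 log2 CPM), where Pecam1 was highest (6.86).

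Fibroblast markers moved by unequal amounts, and a few fell. Of 20 tested, 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median log2 fold change of 0.73 (limma camera adjusted p = 0.000136; adjusted p = 0.613 with an estimated correlation). The collagen I genes Col1a1 and Col1a2 rose by 5.66 (SE 0.15) and 8.62 (SE 0.24), the latter from 1.98 ± 0.60 to 10.59 ± 0.22 log2 CPM (SD, n = 3), the matrix protein gene Postn by 4.64 and Bgn by 5.10. Col3a1, at 12.91 ± 0.14 in the controls, rose by 0.30, a call that several alternatives ended. The 3 that fell were Pdgfra by 0.43, Pdpn by 0.25 and Fbln1 by 0.98. Col3a1 and these 3 were chosen after their values were seen.

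The mesenchymal and extracellular matrix list had 22 of 37 members higher and 8 lower (22 and 9 adjusted over the list alone), with a median log2 fold change of 0.47 (limma camera adjusted p = 0.00112; adjusted p = 0.517 with an estimated correlation). Tnc, the matrix protein tenascin-C, rose by 7.78 (SE 0.13, limma adjusted p = 1.06e-09), the smooth muscle gene Tagln by 6.42, and the collagen crosslinking enzyme gene Loxl2 rose from 0.95 to 4.95 log2 CPM. Snai2, a transcription factor of the epithelial to mesenchymal transition, fell by 2.51 (SE 0.10, limma adjusted p = 8.31e-08). Genes chosen after their values were seen included Acta2, which rose from -0.89 to 5.71 log2 CPM, Fn1, which rose from 13.45 ± 0.09 to 14.79 ± 0.13, and Mmp9 and Vim, which fell by 1.23 and 0.30, and Spp1, which fell from 7.92 to 6.43.

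Immediate early and dissociation stress genes were higher in the libraries labelled Zfx-KO. Of 30 tested, 23 rose and 1, Egr3, fell (23 and 2 adjusted over the list alone), and the median log2 fold change was 1.06 (limma camera adjusted p = 2.88e-07; adjusted p = 0.517 with an estimated correlation). The phosphatase gene Dusp1 rose by 2.69 (SE 0.18, limma adjusted p = 1.61e-06), from 5.23 ± 0.45 to 7.92 ± 0.11 log2 CPM (SD, n = 3), the nuclear receptor gene Nr4a1 by 1.86, Junb by 1.49 and Klf6 by 1.09. Egr3, named after its value was seen, fell by 1.14. In the same libraries the endothelial and pericyte markers were higher.

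Interferon and antigen presentation genes moved by small amounts. In the interferon list 22 of 50 rose and 3 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.20 (limma camera adjusted p = 0.0273; adjusted p = 0.765 with an estimated correlation). With equal medians the median was -0.02, 9 rose and 11 fell, and the call was lost (limma camera adjusted p = 0.336), while with quantile normalization the median was 0.24, 24 rose and 4 fell (0.000113). It was also lost without replicate 1 of the libraries labelled Zfx-KO (adjusted p = 0.12) and without control replicate 2 (0.0736) or 3 (0.0987). The 2'-5' oligoadenylate synthetase genes Oas2 and Oas1a rose by 1.09 and 1.04, the nucleic acid sensor gene Zbp1 by 0.81 (SE 0.07, limma adjusted p = 1.11e-05) and Ifit3 by 0.56, while Mx1, Ifih1 and Ifi44, named after their values were seen, fell by 0.41, 0.25 and 0.41. Of 23 MHC class I presentation genes 10 rose and 1, Canx (named after its value was seen), fell, also adjusted over the list alone (limma camera adjusted p = 0.241). H2-M3 rose by 0.37, B2m by 0.36, Psmb9 by 0.34 and H2-Q7 by 0.30, and with equal medians 0 of the list rose and 7 fell, while with quantile normalization the list passed (adjusted p = 0.0323). None of 7 MHC class II genes passed, over all genes or adjusted over the list alone. H2-DMb1 had a log2 fold change of -0.32 and H2-DMa 0.51, and the median of 0.14 went against the downward direction of the set test (limma camera adjusted p = 0.917). The sign of this median was not stable, with -0.07 with equal medians and 0.71 and -0.46 without control replicates 1 and 2.

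In the NF-kappaB and TNF list 13 of 27 rose and 5 fell, the same adjusted over the list alone (limma camera adjusted p = 0.123). The chemokine genes Ccl5 and Cxcl1 rose by 2.04 (SE 0.12, limma adjusted p = 6.84e-07) and 1.99 (SE 0.12, limma adjusted p = 7.65e-07), the NF-kappaB inhibitor gene Nfkbia by 0.87 and the adhesion molecule gene Vcam1 by 0.84. Csf1, named after its value was seen, fell by 0.98. Without control replicate 1 the list passed (adjusted p = 0.0454), as it did with quantile normalization (0.0054), and with equal medians 11 rose and 9 fell.

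Cell cycle genes were lower in the libraries labelled Zfx-KO. Of 34 G2/M genes 27 fell and 0 rose (28 and 1 adjusted over the list alone), with a median log2 fold change of -0.35 (limma camera adjusted p = 2.88e-07; adjusted p = 0.731 with an estimated correlation). The mitotic kinase genes Cdk1, Ttk and Aurkb fell by 0.59 (SE 0.07), 0.62 (SE 0.11) and 0.35 (SE 0.06), and the kinesin gene Kif23 by 0.54. Of 34 G1/S and replication genes 23 fell and 1, Prim1 (named after its value was seen), rose, also adjusted over the list alone, with a median of -0.30 (limma camera adjusted p = 4.99e-07; adjusted p = 0.517 with an estimated correlation). The transcription factor gene E2f1 fell by 0.90 (SE 0.08, limma adjusted p = 1.32e-05), from 7.06 ± 0.15 to 6.16 ± 0.09 log2 CPM (SD, n = 3), the helicase subunit gene Mcm4 by 0.54 and Rrm2 by 0.48. Both lists were lower under equal medians and quantile normalization too. The endothelial and pericyte markers were higher in the same libraries.

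**Figure D3:**
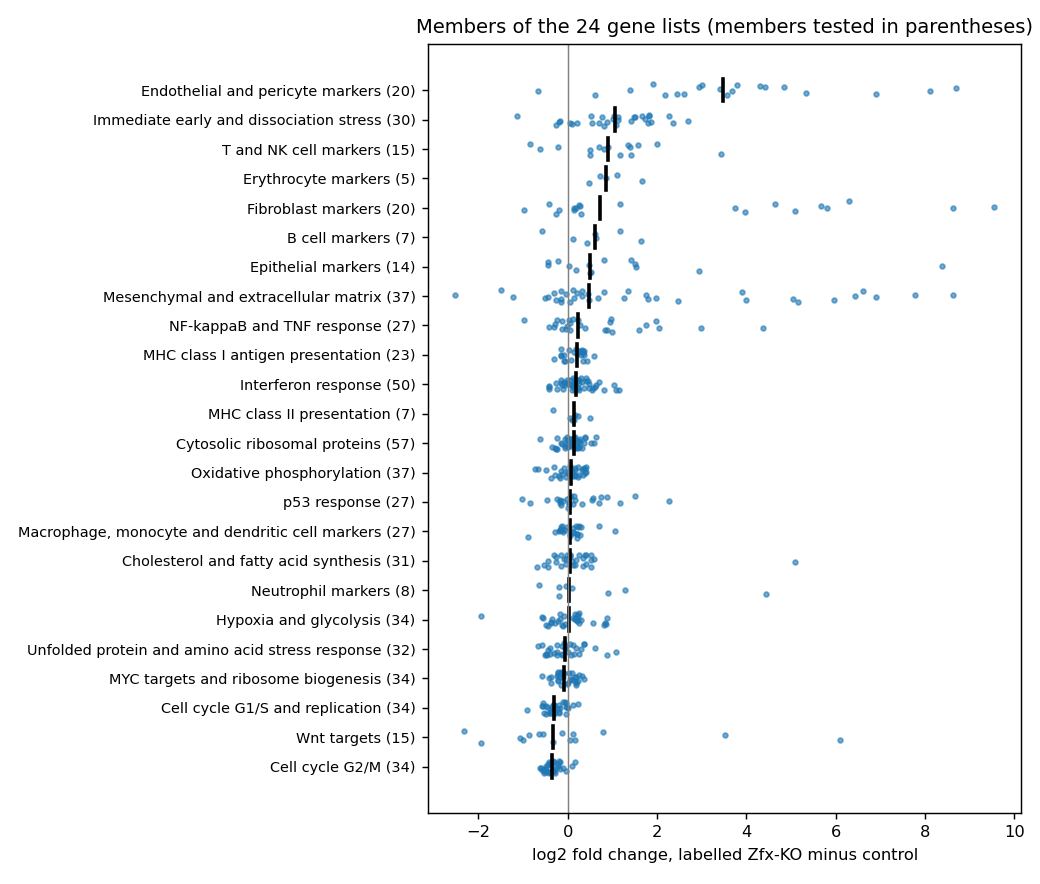
Log2 fold change (libraries labelled Zfx-KO minus control) of each tested member (points) of the 24 gene lists, with the list median as a black bar and the number of members tested in parentheses. Endothelial and pericyte markers have the highest median, 3.49, and G2/M genes the lowest, -0.35; the medians of several lists near 0 change sign with equal medians.

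Lists of growth, stress and metabolism held genes moving both ways, and none of them passed the set test as deposited. With equal medians most of their calls were lower: 0 rose and 18 fell in the MYC list, which then passed (limma camera adjusted p = 0.0162), and 1 and 6 in the ribosomal, 6 and 11 in the p53, 5 and 13 in the hypoxia, 0 and 15 in the oxidative phosphorylation, 3 and 19 in the unfolded protein and 3 and 11 in the cholesterol list. With quantile normalization the oxidative phosphorylation list passed (adjusted p = 0.0406), with 14 and 7. Among 34 MYC targets and ribosome biogenesis genes 7 rose and 10 fell, the same adjusted over the list alone (limma camera adjusted p = 0.339), with Hspd1 at -0.57, Mybbp1a at -0.41, Dkc1 at -0.37 and Ppan at 0.32. Of 57 cytosolic ribosomal protein genes 9 rose and 2 fell (7 and 1 adjusted over the list alone, limma camera adjusted p = 0.342), with Rpl27 at -0.61, Rpl32 at 0.39 and Rps15 at 0.28, and these values are uncertain because reads shared with pseudogene copies appear to have been left out. Of 27 p53 response genes 8 rose and 4 fell, also adjusted over the list alone (limma camera adjusted p = 0.788). The antiproliferative gene Btg2 rose by 2.27 and the cyclin-dependent kinase inhibitor gene Cdkn1a by 0.88, whereas the death receptor gene Tnfrsf10b fell by 1.02 and Ei24 by 0.85.

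Of 34 hypoxia and glycolysis genes 12 rose and 9 fell, also adjusted over the list alone (limma camera adjusted p = 0.788). The median was 0.02, while the mean and the set test pointed down. The HIF hydroxylase gene Egln3 fell by 1.93 (SE 0.09, limma adjusted p = 2.13e-07) and the pyruvate dehydrogenase kinase gene Pdk1 by 0.57, and Bhlhe40 and the phosphofructokinase gene Pfkp rose by 0.89 and 0.86. In the nuclear oxidative phosphorylation list 13 of 37 rose and 8 fell (14 and 8 adjusted over the list alone, limma camera adjusted p = 0.788), and Ndufa8, Ndufv2, Cox5a and Uqcrc2 fell by 0.72, 0.66, 0.48 and 0.36. Of 32 unfolded protein and amino acid stress genes 7 rose and 11 fell (8 and 11 adjusted over the list alone, limma camera adjusted p = 0.265), with Sdf2l1 at 1.09, Creld2 at 0.61, the serine synthesis gene Psat1 at -0.58 and Atf5 at -0.47. Of 31 cholesterol and fatty acid synthesis genes 10 rose and 7 fell, also adjusted over the list alone (limma camera adjusted p = 0.942). The fatty acid synthesis genes Fasn, Acaca and Acly fell by 0.69, 0.52 and 0.44.

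Among 15 Wnt targets 4 rose and 8 fell, the same adjusted over the list alone (limma camera adjusted p = 0.123). The transcription factor gene Lef1 fell by 2.32 (SE 0.09, limma adjusted p = 8.10e-08), the receptor gene Ephb2 by 1.06 and the Wnt inhibitor gene Apcdd1 by 1.00. The stem cell receptor gene Lgr5 had 0 control reads and 219 reads in the libraries labelled Zfx-KO, at least 66.3-fold higher against 3 reads over the group. The list's median of -0.33, the same with Lgr5 at its bound, and its mean of 0.13 differed in sign. Of 14 epithelial markers 3 rose and 1 fell (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.437). The keratin gene Krt8 rose by 8.39 from 5 control reads (7.77 without control replicate 2), Krt19 had 2 control reads and a pooled ratio of 15.9 (interval 4.08 to 136), Muc1 rose by 0.48, a call that several alternatives ended, and the tight junction gene Tjp1 fell by 0.44.

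Markers of blood cells gave few calls. Of 27 macrophage, monocyte and dendritic cell markers 1, the lysozyme gene Lyz2, rose (by 1.07, limma adjusted p = 0.0366), a call that several alternatives ended, and 0 passed adjusted over the list alone. Their median was 0.06, with the set test pointing down (limma camera adjusted p = 0.942), and Fcgr3, Cd14 and Cd68 stood at 0.71, 0.25 and 0.30 without passing. Of 15 T and NK cell markers 2 rose and 1 did so adjusted over the list alone (limma camera adjusted p = 0.342). Cd3d had 1 control read and a pooled ratio of 39.96 (interval 6.81 to 1614), Nkg7 had 3 and 5.15 (1.49 to 27.4), and Klrd1 and Cd8b1, which did not pass, had 6.36 (0.82 to 286) and 9.08 (1.29 to 394). Of 7 B cell markers 2 rose, also adjusted over the list alone, Ighm by 1.64 and Ebf1 by 0.61 (limma camera adjusted p = 0.51). Igkc and Cd79a did not pass. Igkc had 2 control reads and a ratio of 5.90 (1.34 to 53.9), and its log2 fold change of 1.18 was 2.04 and 0.55 without replicates 1 and 3 of the libraries labelled Zfx-KO. Cd79a stood at 0.44. Of 8 neutrophil markers 2 rose, also adjusted over the list alone, Il1r2 by 4.44 (3.75 without control replicate 2) and the histidine decarboxylase gene Hdc by 1.28 (limma camera adjusted p = 0.598), with G0s2 at 0.91 and Trem1 at -0.64 (0.09 and -1.23 without replicates 3 and 1 of the libraries labelled Zfx-KO). Of 5 erythrocyte markers 1 rose, also adjusted over the list alone, Hba-a2 by 1.67 (limma camera adjusted p = 0.342), with Hbb-bs at 0.85, Alas2 at 1.12 and Hbb-bt at 0.71.

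In all, 7 of the 24 lists passed the set test with the preset correlation, and 0 with an estimated correlation for each list. Other divisions of the same 6 libraries gave up to 11 lists past the test with the preset correlation.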

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

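The fits with limma voom on recovered reads and with reads thinned to the shallowest library were chosen after seeing the data; the other alternatives were planned. No paired analysis was run because the labels give no pairs, and replicate numbers here only follow record order. Libraries of the same record order had similar values of the second principal component in the controls and the libraries labelled Zfx-KO (45.9 and 34.8, -43.8 and -32.9, -0.14 and -3.83), so an unrecorded shared factor is possible, and it was not modelled. At each record order Lyz2, Fcgr3, Cd14, Cd68 and H2-DMa were higher, and H2-DMb1 lower, in the labelled library than in the control. These genes were taken from their lists for the smallest p, which favors 1 direction throughout, so they are no evidence of pairs. The macrophage list as a whole had a median of 0.06 and a lower quartile of -0.13. The other members of their lists were not compared in this way. If the libraries are paired, the unpaired tests of genes that vary with the shared factor lose power. Of 2745 values of 162 genes followed over the alternatives, 2655 kept their direction and side of the threshold, 79 fell below it, 10 rose past it and 1 turned: Dcn, chosen after its value was seen and 0.19 as deposited, was -0.0227 with equal medians, which lowers every fold change by 0.21. Zfx stayed higher in the libraries labelled Zfx-KO under every alternative run, with 0.53 to 0.74 when a library was left out, 0.42 with equal medians and 0.70 with quantile normalization.

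With equal medians 3224 genes were higher and 6357 lower, and 1156 were lower by at least 2-fold, against 5003, 3924 and 734. The adjusted p became 0.336 for the interferon list and 0.0162 for the MYC list. With quantile normalization 1540 genes were lower by at least 2-fold, and the MHC class I (0.0323), NF-kappaB (0.0054) and oxidative phosphorylation (0.0406) lists passed. The cause was not tested beyond the shift itself. The stricter filter, which tests fewer genes, left 1509 higher by at least 2-fold against 2332. The interferon list was lost without a variance trend (0.103) and with sample weights (0.142), and the cause was not tested. Over the libraries left out in turn its adjusted p ran from 0.00127 to 0.12 and that of the NF-kappaB list from 0.0454 to 0.217.

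With an estimated correlation 0 lists passed, against 7, with adjusted p of 0.517 for the endothelial, immediate early, mesenchymal and G1/S lists, 0.613 for fibroblast, 0.731 for G2/M and 0.765 for interferon. The correlations between members estimated for those 7 lists were 0.0664 to 0.734, above the preset 0.01. fry, which tests a list by itself and not against other genes, called 14 lists, adding NF-kappaB (0.0214), ribosomal (0.0302), unfolded protein (0.0192), epithelial (0.0248), Wnt (0.00648), T and NK cell (0.00787) and B cell (0.0258). The lowest correlation within a group exceeded the highest between groups by 0.0286, and by 0.0155 without a filter, 0.0449 with the stricter one, and 0.0331 and 0.0244 with the pseudocount times 0.25 and 4.

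Leaving out a library gave 7323 to 8719 genes and 2736 to 2973 with at least a 2-fold difference. limma voom on the recovered reads called 8979 and 3052, and thinning to the shallowest library 8791 and 3030. Depth limits scarce genes most: 3 reads are 0.0461 to 0.0794 CPM, and the deepest library resolves them best.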

Other observations

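The tests in this part were chosen after the results were seen, except the count of other divisions of the libraries and the heterogeneity test of the cell cycle genes. Homeobox and protocadherin genes, which carry positional and cell identity information, gave different counts by cluster, and some clusters were mixed. The clusters were not tested against each other or against all genes, of which 8927 of 20094 passed. Of 6 tested Hoxd genes 4 fell by at least 2-fold and 0 rose, with Hoxd9 down from 5.56 ± 0.07 to 2.70 ± 0.14 log2 CPM (SD, n = 3), Hoxd13 from 4.98 to 2.79, Hoxd10 from 4.28 to 2.33 and Hoxd8 from 5.69 to 4.27. Of 8 tested Hoxb genes 4 rose by at least 2-fold and 0 fell as deposited (with equal medians and with quantile normalization 1 fell). Hoxb9 led them and rose from -3.18 ± 0.59 to 2.84 ± 0.39. Hoxb2, Hoxb7 and Hoxb8 rose but stayed scarce, at -0.26, -2.34 and -2.48 log2 CPM in the libraries labelled Zfx-KO. The other 4 did not pass, among them Hoxb6, at 3.35 in the controls. Of 11 Hoxa genes 1 rose and 3 fell (1 and 8 with equal medians, 0 and 6 with quantile normalization), of 8 Hoxc genes 2 rose and 2 fell (1 and 2, 0 and 3), and of 22 genes of the protocadherin gamma cluster 6 rose and 3 fell (3 and 4, 0 and 3). Of 21 tested genes of the protocadherin beta cluster 19 rose, 16 by at least 2-fold, with a median log2 fold change of 1.52 (1.30 with equal medians and 1.41 with quantile normalization). Pcdhb5 rose by 2.90 and Pcdhb17 by 1.52, while Pcdhb22, the most abundant of those named in the controls, fell by 0.39. Members of this cluster are similar in sequence, and how reads shared between them were counted is not given in the sources used here.

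Imprinted genes, which are expressed from one parental allele, moved both ways, some by large amounts. Of 27 tested from a list written after values were seen, 14 rose and 10 fell (12 and 11 with equal medians, 10 and 11 with quantile normalization), of which 11 rose and 4 fell by at least 2-fold as deposited. No set test was run on them, and the genes named here are among those with larger changes. The abundant noncoding RNA H19 fell by 3.65 (SE 0.10, limma adjusted p = 1.27e-08), from 10.93 ± 0.23 to 7.29 ± 0.02 log2 CPM (SD, n = 3), and its neighbor Igf2 fell by 5.20, as did Peg10 by 3.59. At another imprinted locus Meg3 rose by 8.22 (8.84 and 7.31 without control replicates 1 and 2) and Dlk1, with 0 control reads, was at least 62.1-fold higher against 3 reads over the group. Ndn rose by 5.89 (6.51 without control replicate 3) and Mest by 5.36 (4.75 without control replicate 2). Of 13 protein genes of the mitochondrial genome 9 rose and 0 fell (8 and 0 with equal medians and with quantile normalization), with mt-Nd2 up by 1.05, mt-Nd1 by 0.62 and mt-Cytb by 0.41 (2 alternatives ended the call of mt-Cytb). Control levels ran from -3.22 log2 CPM for mt-Nd3 to 12.26 for mt-Cytb, with mt-Co1 at 9.95 but mt-Co2 at 1.58. Reads shared with copies elsewhere may have been left out, so the values of the low members are uncertain. Many stromal markers were higher in the same libraries, and how much host cells contribute to the homeobox, protocadherin, imprinted and mitochondrial differences was not tested.

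Of the endothelial and pericyte markers 19 of 20 were higher in the libraries labelled Zfx-KO, and of the fibroblast markers 13 of 20. Ramp2 and 3 fibroblast markers fell, and the fibroblast median was only 0.73. A lower purity of the sort that let in every other cell type alike is argued against by the macrophage, monocyte and dendritic cell markers, whose median of 0.0625 and upper quartile of 0.21 lay below the lower quartile of the endothelial and pericyte markers, 2.37. The macrophage median moves when a library is left out, with 0.60 and -0.48 without control replicates 1 and 2, -0.43, 0.45 and 0.25 without replicates 1 to 3 of the libraries labelled Zfx-KO, and -0.15 and -0.35 with equal medians and quantile normalization. For replicates 1 and 2 the control and the labelled library moved it in opposite directions. A factor shared by libraries of the same record order would give this, and none was modelled. Over the libraries left out in turn the upper quartile reached at most 0.78, against a lower quartile of at least 2.08. Of the macrophage markers 22 of 27 exceeded 1 CPM in the controls, and a high level there can hide added cells. Among members between 0 and 5 log2 CPM in the controls, 21 macrophage markers had an upper quartile of 0.23 and 5 endothelial and pericyte markers a lower quartile of 1.40, and the former lay below the latter under both scalings and without each library. The medians of the T and NK cell (0.90 as deposited and 0.18 with quantile normalization), B cell (0.61 and -0.18), erythrocyte (0.85 and 0.34) and neutrophil (0.04 and -0.60) markers changed with the scaling, and the B cell, erythrocyte and neutrophil lists are short. T and NK cell markers stayed scarce, with a median level of -4.53 log2 CPM in the controls and -3.54 in the libraries labelled Zfx-KO. That of the endothelial and pericyte markers went from -1.71 to 2.05. A scarce list cannot hide added cells, so these levels argue against a large addition of T and NK cells. Host stromal cells collected in the sort of the labelled line may contribute. Xist, made from the inactive X of female cells, rose by 2.83 (SE 0.33, limma adjusted p = 6.45e-05), and the hosts were female. The controls already held 361 Xist reads of unknown source. Xist may also differ between the tumor lines, so it does not by itself mark host cells. Among the libraries labelled Zfx-KO, Xist and Rgs5 were lowest in replicate 3 (3.84 and 5.21 log2 CPM). Col1a1 and Col1a2 were highest there (11.66 and 10.83). The collagen I genes thus did not follow Xist over these libraries, and a source shared by both was not shown. In the controls 6 of the 20 endothelial and pericyte markers but 16 of the 20 fibroblast markers exceeded 1 CPM, with 0 of either in another list. Pecam1 at 6.71, Col1a1 at 11.44 and Col1a2 at 10.59 log2 CPM were among the abundant ones in the libraries labelled Zfx-KO. Pecam1 and Col1a1 already stood at 4.27 and 5.78 in the controls. Kdr, chosen after its value was seen, reached only 0.97 in the libraries labelled Zfx-KO, from -3.44. The labels do not name the marker of the sort or the strain of the hosts. A sort on the Thy1 form of the labelled line would also collect host cells that carry this form, and this was not tested. A change of the tumor cells themselves cannot be told apart from this, because 0 libraries separate the Thy1 label from the Zfx genotype.

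Genes lower by at least 2-fold, 734 in number with a median of -1.50, are not accounted for by reads that the risen genes took up, which went from 20.3% to 30.8% of all reads and shift the others by -0.20. Dilution of tumor cells by other cells is argued against as the whole cause by the G2/M genes, none of which lay at or below -1 (lowest -0.62), provided the added cells cycled less than the tumor cells. For the cell cycle lists the reads taken up, or dilution by cells with none of these transcripts, would lower all members equally. Both are argued against as the whole cause, since the members differed (Cochran's Q of 497 on 67 degrees of freedom, which takes them as independent), and 28 of 68 lay below the shift from the reads by over 2 SE, with 10 above it by as much. Either may still account for part of the fall. Dilution by cells that hold some of these transcripts could lower the members unequally, so the test does not bear on it. Q was not compared with that of other gene sets. A difference between the lines that is not due to Zfx stays open, since a single targeted line was compared.

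Zfx reads were higher in the libraries labelled Zfx-KO. A single wrongly labelled library is argued against by the correlations, the lowest within a group exceeding the highest between groups by 0.0286. An exchange of the labels of both groups cannot be told apart from the labels as given: Ptpmt1 at -1.27 and Idh2 at -0.48 lie in the direction of lower Zfx function in the libraries labelled Zfx-KO, but they are 2 genes among 8927 that differed, of which 3924 were lower, and their dependence on Zfx was described in other cells. A transcript that carries an edit and is still made could give such a level, and it was not tested because the reads and the cut site were not used here.

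A hypothesis from the positions of the genes is a copy number difference of chromosome 13 between the cell populations. The 331 protein-coding genes of chromosome 13 with a mean of at least 3 log2 CPM had a median log2 fold change 0.19 above that of the other chromosomes, which is a fold of 1.14, and all 8 windows of 40 genes lay above the median of all 20 chromosomes. A permutation test with random gene sets gave an adjusted p = 6.67e-05, from the smallest p that 100000 permutations can give, 1e-05. Such sets ignore that neighbors vary together, and 8 of 20 chromosomes passed, chromosome 7 with 14 of 16 windows above the median. The offsets of chromosome 13 were 0.11, 0.11 and 0.07 in the libraries labelled Zfx-KO and -0.09, -0.05 and -0.13 in the controls (exact permutation p = 0.1, the smallest possible). The values may also come from other differences between the groups.

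With 10 divisions of the 6 libraries into groups of 3, a share under 0.05 cannot be reached. The real division, the only 1 of the 10 with so many, gave 8927 genes and 3066 with at least a 2-fold difference, and the highest of the others gave 0 of both. For the gene lists 7 of the 10 divisions gave at least the 7 lists of the real one, and the highest of the others gave 11.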
